A study of Escherichia coli with 8 samples.

How the data were processed

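The data are XR-seq libraries from Escherichia coli. XR-seq (excision repair sequencing) reads the short oligonucleotides that nucleotide excision repair cuts out around DNA damage. In bacteria, UvrA and UvrB find the damage, UvrC makes the incisions on both sides of it, and the helicase UvrD releases the excised oligonucleotide. Mfd is a DNA translocase that removes RNA polymerase stalled at damage and brings in the repair proteins, which is known as transcription-coupled repair. Phr is photolyase, which reverses pyrimidine dimers in light. Per the labels' protocols, cells were grown in LB at 37 °C, irradiated with 120 J/m2 of UVC at an OD600 of 0.8 and chilled after 5 minutes. There were 4 strains with 2 libraries each: wild type (WT), phr-, mfd- and uvrD-. The labels number the libraries of each strain as experiments 1 and 2 and do not say that they came from separate cultures. The p-values therefore measure the spread between these samples only, which may be technical.

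The authors deposited, for each library, raw counts of reads per gene on the plus and on the minus strand of the chromosome, 16 tables in all. Per the file names, reads were trimmed with cutadapt, taken to a fixed number per library, aligned with bowtie, limited to reads with a TT dinucleotide and counted over genes by strand. Parameters, versions and the genome build are not given in the sources used here. Reads without TT were not used here, so dimers at other pyrimidine pairs were not measured. Total counts ran from 2441382 to 2619318 reads per library, with a median of 422 to 489 reads per gene. How bowtie placed reads that match several positions is not stated, and this can move reads between strands: 10 unnamed entries of 1017 nt, 8 on the minus and 2 on the plus strand, had 96.8% to 99.6% of their reads on the plus strand. The 22 rRNA entries had 95.6% there, against 55.4% over 4176 named entries outside known multicopy families. Strand ratios of repeated sequence are therefore not interpreted as repair.

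The tables hold 4515 gene entries with start, end, strand and count but no names. Names came from a RefSeq gene table of assembly ASM584v2, a different coordinate set. An entry took the name of the reference gene of the same length whose distance from the entry was shared by at least 4 of the nearest neighbours, 5 on each side. The reference gives no strand, so the strand of an entry was not used to name it. This named 4335 entries (96.0%), of which 235 stood at identical coordinates, with 6 distinct distances along the chromosome. The other 180 stayed unnamed and are given here by position. The genes disrupted in the mutants lost most of their reads in their own mutant, which was a check of these names. All positions below are the start and end in the deposited tables, counted from 1 on a single chromosome, with the last entry ending at 4639651.

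A read is the excised strand itself. Reads on the strand opposite to a gene were taken as template-strand (TS) repair, and reads on the strand of the gene as nontemplate-strand (NTS) repair. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on 16 columns (TS and NTS of each library), with 1 term per library and 1 TS-minus-NTS term per strain, which left 4 residual degrees of freedom. Gene length, copy number and library size cancel in this ratio. The ratio within a strain also holds the unequal number of TT sites on both strands of a gene, which cancels between strains. Genes averaging under 10 reads per library were left out, which removed 37 and left 4478. Total repair was tested as TS plus NTS reads with edgeR and TMM scaling. It is relative within a library, a gene's share of the excised oligonucleotides, and not an absolute amount of repair. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) were taken from the log2 change and its F statistic. Other tools were DESeq2 1.42.0 and limma 3.58.1. On simulated counts with the means and library sizes of the real ones, the edgeR strand test of mfd- against WT recovered 31% of changes of 1 and 90% of changes of 2 on the log2 scale, and called 13 unchanged genes, among 4477 tested. DESeq2 recovered 29% and 87% with 6 false calls, and limma 11% and 82% with 6. The edgeR test of total repair recovered 92% and 100%, with 11 false calls among 4476 genes.

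Gene lists were fixed in 14 groups, with rRNA apart because its copies share reads. The lists were ribosomal proteins, ATP synthase, RNA polymerase with translation factors, respiration with the TCA cycle, glycolysis with the sugar phosphotransferase system, outer membrane proteins, chaperones with heat shock proteases, the LexA regulon, flagella with chemotaxis, cryptic prophage genes, inducible catabolic operons, amino acid biosynthesis, fimbriae with curli and type II secretion, and excision repair with photolyase. Each list was tested on log2((TS + 1)/(NTS + 1)) with camera, which sets a list against all other genes, at a preset correlation of 0.01 and at an estimated one. It was also tested with fry, which asks whether the members move one way on balance. Adjustment was over the 14 lists within each contrast. A simulated fall of 1 in the ribosomal proteins gave an estimate of -0.90 and was called by camera (adjusted p = 5.68e-32), with 0 of the 13 other lists called. With an estimated correlation camera called 1 of the lists.

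The genes named were chosen by rule. They are the 10 largest rises and 10 largest falls of the strand ratio per strain among genes past the threshold, with both mutant libraries beyond both WT libraries and at least 100 reads per library on average. For total repair the rule took 5 and 5 by the same criteria, and for TS against NTS in WT the 5 highest and 5 lowest. The 3 most read members of each list, the disrupted genes, uvrA, uvrB, uvrC, recA, lacZ and lacI were always included. The groups, tests, lists, naming rule and alternatives were chosen before the data were examined. Single comparisons over libraries used exact two-sided permutation tests. With 2 libraries against 2 such a test has 6 assignments and cannot give a p under 0.333. Alternatives were other tools, added reads of 1 or 5, other minimum counts, multicopy genes left out, other scalings, the strains compared alone, the experiment number as a block, and each library left out in turn. Leaving out 1 library leaves a strain with 1, which is then assumed to vary like the others. Whether the experiment numbers pair the libraries was checked from the correlation of deviations from the strain means across genes. For total reads all 6 pairs of strains were above 0.1 (0.171 to 0.543), so the numbers pair the libraries there. The main fit of total repair nonetheless left this pairing out, and the block is given as an alternative. For the strand ratio 2 of the 6 pairs were below 0.1, both with uvrD- (0.090 for WT and 0.074 for mfd-), while the 3 pairs among WT, phr- and mfd- were 0.345 to 0.385. Pairing was taken only where every pair was above 0.1, so the numbers were not taken as pairing the strand ratio. The pairing comes from the labels' experiment numbers. Intervals and bounds cover counting error only.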

Results

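Excised oligonucleotides carrying TT were counted on each strand of 4478 genes in 8 libraries, 2 from each of WT, phr-, mfd- and uvrD- cells, 5 minutes after 120 J/m2 of UVC. Depth was close to even, from 2441382 reads in phr- experiment 1 to 2619318 in uvrD- experiment 2. Libraries of 1 strain differed by more than sampling noise, with chi-square per degree of freedom of 8.17 (mfd-) to 17.2 (phr-). Spearman correlations of the strand ratio between the libraries of a strain, across genes, were 0.918 to 0.937. The series title names transcription-coupled repair by Mfd, and the comparisons ask how the template-strand preference of repair depends on each mutated gene.

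The disrupted genes were checked first. The photolyase gene phr (positions 738730 to 740148) had 183 and 151 reads in the phr- libraries and 544 to 932 in the others. The mfd gene (1169741 to 1173187) had 393 and 464 reads in mfd- and 1628 to 2178 elsewhere. The helicase gene uvrD (3996006 to 3998168) had 205 and 173 reads in uvrD- and 1156 to 1701 elsewhere. Relative to library size these were 27.4%, 25.5% and 11.4% of the WT level (n = 2 libraries per strain). Each gene was thus lowest in the libraries of its own mutant, but reads were still assigned to it there.

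In WT cells the genes of protein synthesis had the strongest excess of template-strand repair. The median TS/NTS of the 54 ribosomal protein genes was 8.04-fold (log2 3.01 ± 0.20, SD over libraries, n = 2). RNA polymerase and translation factors stood at 4.73-fold (2.24 ± 0.05) and outer membrane proteins at 3.67-fold (1.88 ± 0.27). ATP synthase genes stood at 3.40-fold (1.76 ± 0.22) and chaperones with heat shock proteases at 3.32-fold (1.73 ± 0.24). Inducible catabolic operons, whose genes are mostly silent without their substrate, had more NTS than TS reads, at 0.757-fold (-0.40 ± 0.15). This list stood at -0.36 in phr-, -0.37 in mfd- and 0.11 in uvrD-. Ratios within a strain were not corrected for unequal TT sites, so its WT value is not read as a preference of repair. Fimbrial and type II secretion genes (0.03 ± 0.11) and amino acid biosynthesis genes (0.13 ± 0.29) were near equality.

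Gene by gene, edgeR called 1910 genes with TS above NTS and 1231 with NTS above TS in WT, with a median of 1.21-fold over the 4478 genes. TS was above NTS in 49 of 54 ribosomal protein genes, 17 of 20 RNA polymerase and translation factor genes, 15 of 16 chaperone genes, 13 of 16 glycolytic genes and 10 of 11 outer membrane genes, with 0 called the other way. Adjusted over the list alone, the ribosomal proteins gave 49 higher and 1 lower, and the other 4 lists gave the same counts. These 5 lists stood above all other genes by camera, with adjusted p = 3.30e-10 for ribosomal proteins (TS-ward in both libraries), 6.44e-04 for RNA polymerase and translation factors and for chaperones, 0.00269 for outer membrane proteins and 0.00377 for glycolysis. Each of the 5 had adjusted p = 0.351 with an estimated correlation. Catabolic operons had 19 members higher and 26 lower of 65 (19 and 27 adjusted over the list alone) and stood below other genes by camera (adjusted p = 0.0196). That call had adjusted p = 0.416 with an estimated correlation. ATP synthase (7 higher and 1 lower of 9), respiration (22 and 5 of 36), the LexA regulon (19 and 5 of 29), flagella (27 and 9 of 52) and excision repair (5 and 1 of 9) did not pass against other genes, with camera adjusted p of 0.0653, 0.0663, 0.0653, 0.0653 and 0.246. Without WT experiment 2 the first 4 of these had camera adjusted p = 0.0423. The LexA regulon had camera adjusted p = 0.0243 with the excess of plus-strand reads removed, an alternative added after the data were seen, and in the main fit adjusted p = 0.416 with an estimated correlation. Prophage genes (25 higher and 17 lower of 79), amino acid biosynthesis (22 and 18 of 58) and fimbriae (16 and 15 of 63) were split, with camera adjusted p of 0.886, 0.728 and 0.260. Adjusted over the list alone, the LexA regulon gave 20 and 6, prophage genes 24 and 16, amino acid biosynthesis 22 and 16, fimbriae 14 and 15, and the others the same counts.

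The recombinase gene recA (2820730 to 2821791), which the SOS response induces, had 745 and 813 TS against 36 and 25 NTS reads in WT (log2 4.67, SE 0.253, edgeR adjusted p = 2.05e-08). The damage recognition gene uvrA (4269072 to 4271894) stood at 2.53 and the incision gene uvrC at 1.14, both past the edgeR threshold. The values were 0.52 for uvrB (edgeR adjusted p = 0.0613), -0.31 for lacZ (0.148) and 0.39 for the lac repressor gene lacI (0.0626). The most extreme ratios lay mainly in short or repeated sequence. The overlapping small entries tpr and rttR had 1245 TS to 1 NTS read and 1347 to 2, summed over both libraries, ratios of 1240 (95% interval 223 to 49200) and 674 (186 to 5570). Reads in the shared part of these entries cannot be told apart, so both are uncertain. The next highest were 1017-nt unnamed entries at 2064329 to 2065345 (8.63), 2099919 to 2100935 (8.40, and 13.06 without WT experiment 2) and 573960 to 574976 (8.39), and another of that length, at 1394100 to 1395116, was among the lowest (-5.14). Entries of this length had at least 96.8% of reads on the plus strand whichever way they faced, so their ratios are uncertain. At the other end, unnamed entries at 887199 to 887277 and 3578950 to 3579039 had 0 TS and 186 and 136 NTS reads, at least 62-fold and 45.3-fold toward NTS against a floor of 3 reads over both libraries. The small genes ytjA (-6.09) and yjeO (-5.27) followed. Reads on the plus strand exceeded those on the minus strand in every library, by 0.27 to 0.42 on the log2 scale. With this excess removed, an alternative added after the data were seen, lacZ in WT stood at -0.68 (edgeR adjusted p = 0.00403) and uvrB at 0.90 (0.00539).

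**Figure D1:**
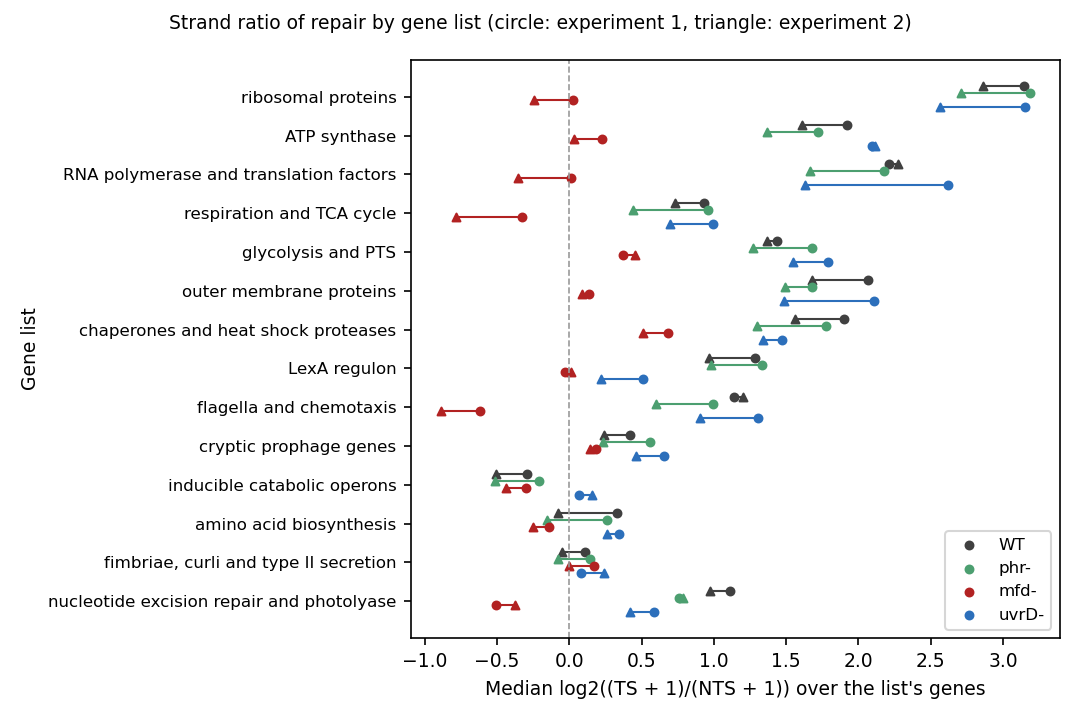
Median log2((TS + 1)/(NTS + 1)) over the genes of each list (x axis) for 14 gene lists (y axis), with 1 symbol per library (circle experiment 1, triangle experiment 2) and 1 colour per strain; lines join the libraries of a strain. Ribosomal proteins lie at a mean of 3.01 in WT, 2.95 in phr-, -0.11 in mfd- and 2.86 in uvrD-.

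The strand ratio was close to that of WT in phr- cells. Ribosomal protein genes stood at 7.72-fold TS over NTS (log2 2.95 ± 0.34, n = 2), the LexA regulon at 1.16 against 1.13 in WT, and catabolic operons at -0.36 against -0.40. EdgeR called 1840 genes higher and 1290 lower on the TS within phr-. Against WT, edgeR called 0 genes changed, with 101 at an unadjusted p under 0.05. DESeq2 called 0 (44 unadjusted) and limma 0 (115 unadjusted), and edgeR called 2 without phr- experiment 1. Camera placed 4 lists apart from other genes by small shifts of the mean: respiration by -0.20 (adjusted p = 0.00908), outer membrane proteins by -0.30 (0.00956), flagella by -0.16 (0.0397) and fimbriae by 0.17 (0.00908). With an estimated correlation they had adjusted p = 0.733, 0.588, 0.855 and 0.588, and fry called none of the 14 lists (smallest adjusted p = 0.602). All 4 calls were lost without WT experiment 1 (camera adjusted p of 0.438, 0.255, 0.438 and 0.0754) and without phr- experiment 2 (0.280, 0.137, 0.931 and 0.137). Respiration shifted by -0.117 and -0.135 in these, and flagella by -0.092 and 0.003. Flagella shifted by -0.321 without phr- experiment 1. Outer membrane proteins were also lost without phr- experiment 1 (0.122), and fimbriae without WT experiment 2 (0.109) or phr- experiment 1 (0.0893). No member of any list was called in phr-, by edgeR over all genes or adjusted over the list alone.

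The template-strand share of repair was lower in mfd- than in every other library. TS reads were 44.35% and 42.52% of reads in mfd-, against 57.41% and 55.61% in WT, 56.87% and 52.87% in phr-, and 57.47% and 54.50% in uvrD-. The mean was 43.4% ± 1.29 (SD, n = 2) in mfd- and 55.8% ± 1.84 (n = 6) in the strains with Mfd. The difference was -12.4 percentage points (exact two-sided permutation p = 0.0357, the smallest that 28 assignments can give). This test took the 8 libraries as separate units, although those of a strain may not come from separate cultures. The share was higher in experiment 1 than in experiment 2 in all 4 strains, and permuting strains within each experiment gave an exact permutation p of 0.0625, the smallest that 16 assignments can give. Leaving out 1 mfd- library left a difference of -13.3 (without experiment 1) or -11.4 points (without experiment 2), where the exact permutation p was 0.143 with 7 assignments, the smallest that test can give.

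**Figure D2:**
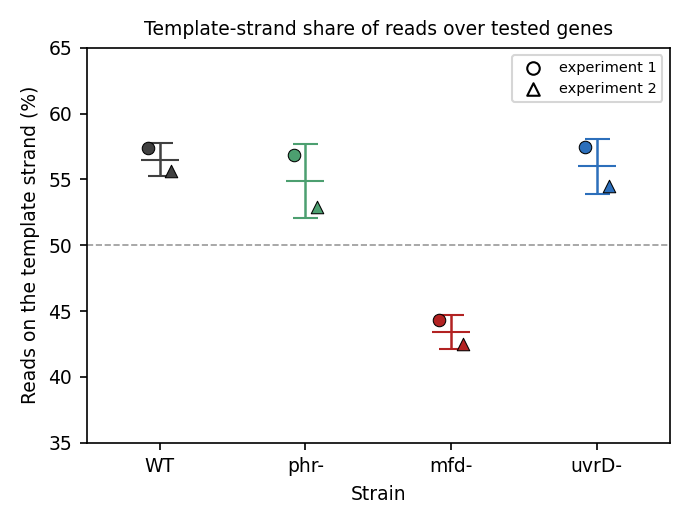
Percentage of reads on the template strand over the tested genes (y axis) for each library of the 4 strains (x axis); circles are experiment 1, triangles experiment 2, and bars the mean ± SD of 2 libraries. The mfd- libraries lie at 44.35% and 42.52%, and the lowest of the other 6 at 52.87%.

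In mfd- cells the lists with the strongest template-strand repair in WT lost most of it by their medians, while single genes differed. On the log2 scale recA (4.67 in WT) kept 2.75, yafN (7.09) kept 4.97 and tpiA (3.93) kept 3.24. Against this, secG (4.76 in WT) stood at -0.11 and rpmB (4.40) at -0.85. Ribosomal protein genes fell to 0.928-fold TS over NTS (log2 -0.11 ± 0.19, n = 2) from 8.04-fold, and 49 of 54 fell individually. RNA polymerase and translation factors went from 4.73-fold to 0.888-fold, outer membrane proteins from 3.67-fold to 1.08-fold, ATP synthase genes from 3.40-fold to 1.09-fold and flagellar genes from 2.25-fold to 0.592-fold. Glycolytic genes and chaperones kept a median above 1, at 1.33-fold and 1.51-fold. Catabolic operons (-0.37 ± 0.10 against -0.40 ± 0.15) and fimbrial genes (0.08 ± 0.12 against 0.03 ± 0.11) differed from WT by less than the SD of the libraries.

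EdgeR called 1450 genes lower and 63 higher in TS/NTS in mfd- than in WT, 33.8% of those tested, with a median change of -0.52 over all genes. Within mfd-, 1062 genes had TS above NTS and 1966 the opposite. Of the genes called TS-ward in WT, 977 fell in mfd- and 6 rose, and of those called NTS-ward, 141 fell and 42 rose. These counts share the WT libraries, whose chance values alone push high genes down and low genes up. Genes were therefore also picked by their ratio in phr-, a step added after the data were seen: the highest 448 had a median mfd- change of -1.54 and the lowest 448 of -0.11.

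Among ribosomal protein genes, 0 rose and 49 fell (0 and 52 adjusted over the list alone; camera adjusted p = 9.44e-17). The call had adjusted p = 0.135 with an estimated correlation. Fry called the list lower (adjusted p = 9.12e-04). The largest falls by the naming rule included rpmB (positions 3809461 to 3809697, ribosomal protein L28), at -5.25 (SE 0.357, edgeR adjusted p = 1.70e-06). Its TS reads were 667 and 402 in WT and 38 and 38 in mfd-, and its NTS reads 34 and 17 against 61 and 77. Other ribosomal protein genes among the 10 largest falls were rpsT (-5.20), rplN (-5.10) and rpmF (-6.12). The value of rpmF rests on 2 NTS reads in WT and was -3.89 in limma with 5 reads added. Of the most read members, rplA fell by 3.24 and rpmA by 4.58, while rplB stood at -0.77 (edgeR adjusted p = 0.0512). The protein translocase gene secG (3320195 to 3320527) went from 2034 and 1758 TS reads to 140 and 91, with NTS reads of 97 and 48 against 155 and 95 (-4.86, SE 0.305, edgeR adjusted p = 1.09e-06). The transfer-messenger RNA gene ssrA (2753615 to 2753977), whose RNA rescues stalled ribosomes, fell by 4.78 and the ribosome maturation gene rimM by 4.83. The small genes uof (-5.67), yceD (-4.73) and yrbN (-4.70) completed the 10.

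Of the other lists, RNA polymerase and translation factors had 19 of 20 lower (20 adjusted over the list alone, camera adjusted p = 4.26e-06). In the same terms ATP synthase had 8 of 9 (9, 0.00136), respiration 27 of 36 (31, 3.40e-05) and outer membrane proteins 10 of 11 (11, 9.60e-05). Chaperones had 12 of 16 (15, 0.00215) and glycolysis 10 of 16 (12, 0.0363), with 0 higher in any of these lists. With an estimated correlation these had adjusted p = 0.169, 0.135, 0.228, 0.152, 0.216 and 0.228. Fry called each lower (adjusted p = 0.00153, 0.00105, 0.00249, 9.12e-04, 0.00173 and 0.00213). The glycolysis call was also lost without WT experiment 1 (0.0823), mfd- experiment 1 (0.0575) or mfd- experiment 2 (0.0640). Examples were the RNA polymerase subunit gene rpoB (-1.25), the initiation factor gene infB (-1.36), the ATP synthase genes atpA (-1.84) and atpF (-2.58), the succinate dehydrogenase gene sdhA (-1.87), the aconitase gene acnB (-1.84), the lipopolysaccharide export gene lptD (-1.55), the gene tolB of the Tol system (-1.89) and the protease genes clpX (-2.42) and ftsH (-1.64). Other most read members passed with all libraries but not without single ones, with edgeR adjusted p as follows. The ATP synthase gene atpD (-0.91) was lost without WT experiment 1 (0.0616), WT experiment 2 (0.0940) or mfd- experiment 2 (0.192). The polymerase gene rpoC (-0.86) was lost without WT experiment 1 (0.203) or 2 (0.0656), mfd- experiment 2 (-0.52, 0.352), or uvrD- experiment 1 (0.0692) or 2 (0.0696). The NADH dehydrogenase gene nuoG (-0.78) was lost without WT experiment 1 (-0.45, 0.356), mfd- experiment 1 (0.0550) or 2 (0.279), or uvrD- experiment 1 (0.0591) or 2 (0.0586). The glycolytic gene pgk (-1.20) was lost without WT experiment 1 (-0.54, 0.354), mfd- experiment 2 (0.244), or uvrD- experiment 1 (0.0571) or 2 (0.0567), and stood at -2.02 without WT experiment 2. The glycolytic gene pgi (-0.84) was lost without WT experiment 2 (0.0622) or mfd- experiment 1 (0.106), the chaperone gene clpB (-0.91) without WT experiment 1 (0.0646) or mfd- experiment 2 (0.0548), and the outer membrane assembly gene bamA (-1.12) without mfd- experiment 2 (0.0552). In limma, rpoC, nuoG and pgk did not pass with all libraries (adjusted p of 0.109, 0.1002 and 0.0736 with 1 read added, and 0.0897, 0.0856 and 0.0549 with 5). The triose phosphate isomerase gene tpiA stood at -0.69 (edgeR adjusted p = 0.0792).

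Damage response and motility genes also fell in mfd-. The LexA regulon had 15 of 29 lower (18 adjusted over the list alone; camera adjusted p = 9.36e-04, and adjusted p = 0.169 with an estimated correlation). In it recA fell by 1.93 (SE 0.365, edgeR adjusted p = 0.00132), with TS reads of 187 and 220 against 745 and 813 in WT, and uvrA by 1.77 (SE 0.262, 2.66e-04). The septum translocase gene ftsK (-1.69) and the DNA polymerase II gene polB (-1.61) fell as well. Flagellar and chemotaxis genes had 38 of 52 lower (44 adjusted over the list alone; camera adjusted p = 8.56e-08), a call with adjusted p = 0.228 with an estimated correlation. The basal body gene fliF fell by 3.18 and the chemoreceptor genes aer and tar by 2.23 and 1.60. In the excision repair list 7 of 9 were lower, also adjusted over the list alone, with camera adjusted p = 0.0636 against other genes. They included uvrB (-1.72), uvrC (-1.61) and uvrD (-1.67), while phr stood at -0.35 (edgeR adjusted p = 0.366). The disrupted gene mfd is also a member and counts among the 7. By fry the LexA regulon, flagella and excision repair were lower in mfd- (adjusted p = 0.00105, 0.00388 and 3.79e-04). Reads left at the disrupted mfd gene gave -0.82, a call lost without either WT library or without mfd- experiment 2 (edgeR adjusted p of 0.0890, 0.0536 and 0.214). The polymerase I gene polA (-0.88) was lost without WT experiment 1 or mfd- experiment 2 (edgeR adjusted p of 0.0605 and 0.0675).

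The lists of catabolic operons, fimbriae and prophage genes stood above the other genes in mfd-, whose median fell, while few of their own members changed. Catabolic operons had 2 higher and 1 lower of 65 (2 and 0 adjusted over the list alone), with a median change of 0.00 and a mean 0.77 above other genes (camera adjusted p = 4.92e-08). That call had adjusted p = 0.135 with an estimated correlation. Fimbriae had 2 higher and 0 lower of 63 (0 and 0 adjusted over the list alone), a median of 0.00 and a mean 0.75 above others (camera adjusted p = 4.92e-08). That too had adjusted p = 0.135 with an estimated correlation, and fry gave adjusted p = 0.638 for both. Prophage genes had 4 higher and 3 lower of 79 (4 and 2 adjusted over the list alone), with a median change of -0.16 and a mean 0.59 above others (camera adjusted p = 4.26e-06). This was the 1 list call of 32 over all contrasts that held with an estimated correlation (adjusted p = 0.0494), and fry gave adjusted p = 0.0822. Among the most read members, lacZ (-0.06, edgeR adjusted p = 0.898), rhaA (-0.15, 0.797), ybgQ (0.00, 1.0), elfC (-0.14, 0.721) and yraJ (0.36, 0.298) did not pass. The beta-glucoside transporter gene bglF rose by 1.06 (SE 0.220, edgeR adjusted p = 0.00231). The prophage genes intD (1.03) and ydfT (1.08) passed, but not without mfd- experiment 1 (edgeR adjusted p of 0.0612 and 0.0868), nor intD without WT experiment 2 (0.0538). The prophage gene ymfD stood at 1.21 (edgeR adjusted p = 0.0636). Amino acid biosynthesis had 0 higher and 8 lower of 58 (0 and 6 adjusted over the list alone), with camera adjusted p = 0.142 and fry adjusted p = 0.0313 (lower). In it lysA stood at -0.05 (edgeR adjusted p = 0.897) and the methionine synthase gene metH at 0.01 (0.989). Its phosphatase gene serB (-1.13) was lost without WT experiment 2 or mfd- experiment 1 (edgeR adjusted p of 0.107, and 0.187 with a value of -0.67), and in limma with 1 read added (adjusted p = 0.0638).

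Of the 63 genes whose TS/NTS rose in mfd-, the ethanolamine ammonia-lyase gene eutB (2555340 to 2556701) rose by 2.58 (SE 0.263, edgeR adjusted p = 2.28e-05). Its TS reads were 252 and 303 in WT and 554 and 461 in mfd-, and its NTS reads 387 and 392 against 119 and 119. An unnamed entry at 3309247 to 3309420 rose by 3.79 (SE 0.563), the DNA polymerase III subunit gene holE by 2.32, the prophage gene ymfL by 2.32 and the gene yjaZ by 1.97. The toxin gene hokA (2.13) and mokA (2.41) also passed, but they overlap each other on the same strand and share reads. The remaining 3 of the 10 were lost without single libraries, with edgeR adjusted p as follows. The prophage gene ymfM (1.97) was lost without WT experiment 2 (0.0860) or mfd- experiment 1 (1.18, 0.151), yceQ (1.85) without WT experiment 1 (0.171) or mfd- experiment 2 (0.0929), and yjbJ (1.85) without WT experiment 2 (0.262), mfd- experiment 1 (0.235) or mfd- experiment 2 (0.0515). With all libraries yjbJ did not pass in DESeq2 (adjusted p = 0.0524) or in limma with 1 read added (0.0647).

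**Figure D3:**
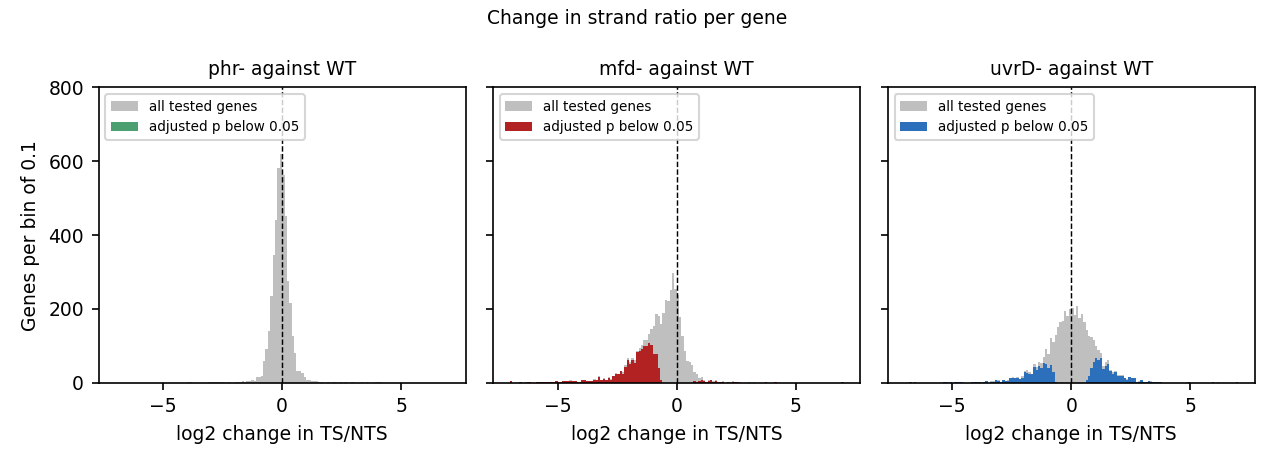
Number of genes (y axis) per bin of 0.1 in the log2 change of TS/NTS against WT (x axis) for phr-, mfd- and uvrD-; grey bars are all 4478 genes, with values beyond the axis range placed in the end bins, and coloured bars those with an edgeR adjusted p below 0.05. The called genes number 0 in phr-, 1513 in mfd- (1450 lower) and 1310 in uvrD- (626 lower).

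In uvrD- cells the template-strand share was 56.0% ± 2.10 against 56.5% ± 1.27 in WT (SD, n = 2 each), while single genes moved both ways. Ribosomal protein genes stood at 7.25-fold TS over NTS (log2 2.86 ± 0.42, n = 2) and ATP synthase genes at 4.30-fold (2.11 ± 0.01), against 8.04-fold and 3.40-fold in WT. The LexA regulon stood at 1.29-fold (0.36 ± 0.20) against 2.18-fold, and catabolic operons at 1.08-fold (0.11 ± 0.06) against 0.757-fold. EdgeR called 684 genes higher and 626 lower than in WT, 29.3% of those tested, with a median change of 0.05. The total of 1310 was 719 without WT experiment 2, 638 without uvrD- experiment 1 and 606 without uvrD- experiment 2. Within uvrD-, 1852 genes had TS above NTS and 933 the opposite, 2785 in all and 1816 without uvrD- experiment 1.

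Of the genes called NTS-ward in WT, 474 rose in uvrD- and 19 fell, and of those called TS-ward, 519 fell and 61 rose. The WT libraries stand on both sides of these counts too. Picked by their ratio in phr- instead, the highest 448 genes had a median uvrD- change of -1.08 and the lowest 448 of 1.09. The ribosomal protein gene rplO (3442127 to 3442561) rose by 5.00 (SE 0.563, edgeR adjusted p = 1.54e-04), with TS reads of 174 and 173 in WT and 207 and 183 in uvrD-, and NTS reads of 280 and 297 against 9 and 11. The type II secretion genes pppA (3.69), the prepilin peptidase gene, and gspG (3.54) rose, as did the cytochrome c maturation gene ccmC (3.51), the disulfide isomerase gene dsbG (3.49), the maltose regulon gene malM (3.24) and the thymidylate kinase gene tmk (3.20). The genes ytjA (3.33), ogrK (3.30) and yfaE (3.21) completed the 10. The largest fall was that of an unnamed 66-nt entry at 3698159 to 3698224 (-6.75, SE 0.486, edgeR adjusted p = 2.02e-05), with TS reads of 2409 and 2099 in WT and 31 and 39 in uvrD-. The antitoxin gene yafN (252005 to 252298), of the LexA regulon, fell by 5.24, with TS reads of 1272 and 811 against 99 and 96. The genes lptM (-4.83), uof (-4.72), fliL of the flagellar motor (-3.86), bolA (-3.82), ybeD (-3.66) and the molybdenum cofactor gene moaC (-3.50) fell, as did unnamed entries at 289653 to 289857 (-4.63) and 279651 to 279959 (-3.34).

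The LexA regulon was the 1 list that camera placed apart in uvrD-, with 2 members higher and 12 lower of 29 (3 and 12 adjusted over the list alone; adjusted p = 0.0216). It had adjusted p = 0.881 with an estimated correlation, adjusted p = 0.0413 by fry, and 0.0552 by camera without WT experiment 1. In it uvrA fell by 1.73 (SE 0.263, edgeR adjusted p = 7.24e-04) and polB by 1.45. The regulon also holds uvrD, the gene disrupted here, whose TS/NTS was 1.66 in WT and -0.43 in uvrD-. The list was not tested without uvrD. The recA value was -1.56 (edgeR adjusted p = 0.00730), lost without WT experiment 2 (-1.25, 0.0649) or uvrD- experiment 2 (-1.35, 0.0780), and ftsK stood at -0.24 (0.400). Ribosomal proteins had 3 higher and 10 lower of 54 (3 and 9 adjusted over the list alone; camera adjusted p = 0.336), among them rplB, which rose by 2.49, while rplA (0.45) and rpmA (-1.37) did not pass (edgeR adjusted p of 0.535 and 0.0675). Catabolic operons had 17 higher and 5 lower of 65 (18 and 5 adjusted over the list alone; camera adjusted p = 0.268), with lacZ up by 1.40 (SE 0.259, edgeR adjusted p = 0.00225), bglF at 0.34 (0.267) and rhaA at 0.99 (0.0389, lost without WT experiment 1 or 2, 0.0586 and 0.190, or uvrD- experiment 1 or 2, 0.173 and 0.125, and in limma with 1 or 5 reads added, 0.0945 and 0.0746). Fimbriae had 15 higher and 2 lower of 63, also adjusted over the list alone (camera adjusted p = 0.416), with ybgQ at 0.90 (edgeR adjusted p = 0.0541), elfC at -0.52 (0.103) and yraJ at -0.37 (0.273). Flagellar genes had 11 higher and 7 lower of 52 (12 and 7 adjusted over the list alone), with aer up by 2.25, fliF at -1.26 (not past without uvrD- experiment 2, edgeR adjusted p = 0.0828) and tar at -0.24 (0.632). Counts were 2 higher and 8 lower for chaperones (camera adjusted p = 0.268), 12 and 8 for prophage genes, 6 and 6 for respiration, 6 and 8 for amino acid biosynthesis, 3 and 1 for RNA polymerase and translation factors, 3 and 0 for glycolysis, 2 and 0 for ATP synthase, 2 and 1 for outer membrane proteins, and 2 and 3 for excision repair. In the last, uvrB stood at -0.13 (edgeR adjusted p = 0.806) and uvrC at 0.03 (0.943). Fry also called excision repair lower (adjusted p = 0.0413), against a camera adjusted p of 0.416. This list too holds the disrupted uvrD gene (1.66 in WT, -0.43 in uvrD-) and was not tested without it. The regulator gene lacI stood at 0.83 (edgeR adjusted p = 0.0246), lost without either WT library or uvrD- experiment 1 (0.0606, 0.127 and 0.191).

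Against WT, 354 genes had a lower TS/NTS in both mfd- and uvrD-, uvrA and clpX among them, 32 a higher one in both, 122 a lower one in mfd- and a higher one in uvrD-, and 2 the reverse. Both contrasts use the same WT libraries, so shared calls are not independent of each other. Tested directly, mfd- had a lower TS/NTS than uvrD- in 1862 genes and a higher one in 292. The total of 2154 was 1398 without mfd- experiment 2 and 1353 without uvrD- experiment 1. Ribosomal proteins were lower in mfd- in 47 of 54 members (48 adjusted over the list alone; camera adjusted p = 1.49e-09), flagella in 40 of 52 (41; 5.39e-06), RNA polymerase and translation factors in 16 of 20 (18; 6.03e-04), ATP synthase in 9 of 9 (9; 0.00117), respiration in 28 of 36 with 2 higher (30 and 2; 0.00209) and outer membrane proteins in 9 of 11 (9; 0.00365). With an estimated correlation these had adjusted p = 0.344, 0.385, 0.347, 0.261, 0.385 and 0.344. Fry called each lower (adjusted p = 0.00117, 0.00411, 0.00177, 0.00117, 0.00251 and 0.00117). Prophage genes (8 higher and 12 lower), catabolic operons (7 and 18) and fimbriae (8 and 16) stood above other genes in mean although more of their members were lower (camera adjusted p of 0.0170, 0.0165 and 0.00344). They had adjusted p = 0.261, 0.385 and 0.344 with an estimated correlation, and 4 and 8, 7 and 17, and 8 and 16 members adjusted over the list alone. The prophage call had camera adjusted p = 0.103 with at least 50 reads required. Fry gave adjusted p = 0.00809 for prophage genes (lower), 0.110 for catabolic operons and 0.116 for fimbriae. Glycolysis (0 higher and 10 lower, camera adjusted p = 0.0838) and the LexA regulon (3 and 11, 0.653) did not pass by camera. Nor did chaperones (0 and 7), amino acid biosynthesis (6 and 14) and excision repair (0 and 5). These 5 had the same counts adjusted over the list alone. By fry, which does not set them against other genes, they were lower in mfd- (adjusted p = 0.00177, 0.0120, 0.00694, 0.0245 and 0.00117). Excision repair holds both disrupted genes, mfd (-0.675) and uvrD (0.414), and the LexA regulon holds uvrD.

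Total repair per gene, TS plus NTS relative to the rest of the library, was lower in many ribosomal protein, flagellar, RNA polymerase and LexA regulon genes in mfd-, and in many in uvrD-. The median log2 change of the ribosomal protein genes was -1.14 in mfd-, with 33 of 54 lower (41 adjusted over the list alone), and -1.47 in uvrD-, with 47 lower (48). Flagellar genes had medians of -0.45 (21 of 52 lower, 25 adjusted over the list alone) and -0.98 (41 lower and 1 higher, also adjusted over the list alone). RNA polymerase and translation factors had -0.59 (12 of 20 lower, 15 adjusted over the list alone) and -0.78 (14, and 16), and the LexA regulon -0.42 (10 of 29 lower, 12 adjusted over the list alone) and -0.69 (19, and 19). Catabolic operons had 0.37 in mfd- (2 higher, 1 adjusted over the list alone) and 0.21 in uvrD- (18 higher and 3 lower; 16 and 3), and fimbriae 0.30 (1 higher; 0) and 0.29 (21 higher and 8 lower; 22 and 8). With library totals in place of TMM, catabolic operons had 10 higher in mfd- and 27 in uvrD-, and fimbriae 5 and 28. Glycolytic genes had 4 lower and 0 higher in mfd- but 3 lower and 4 higher in uvrD-, and chaperones 5 and 0 against 5 and 3. Adjusted over the list alone, glycolysis gave 5 and 0 against 4 and 4, and chaperones 5 and 0 against 5 and 4. Camera was added for these totals after the data were seen, and none of its calls held with an estimated correlation. In mfd- it placed ribosomal proteins (adjusted p = 6.39e-24), RNA polymerase and translation factors (7.75e-08), the LexA regulon (5.58e-05), outer membrane proteins (6 of 11 lower, 7 adjusted over the list alone; 2.06e-04) and excision repair (5 of 9 lower, also adjusted over the list alone; 0.00376) below other genes, each with adjusted p = 0.0962 with an estimated correlation. Flagella (5.47e-09), chaperones (0.00289), glycolysis (0.0182) and respiration (4 of 36 lower, 6 adjusted over the list alone; 0.0220) also stood below, with adjusted p = 0.223, 0.244, 0.371 and 0.347 with an estimated correlation. Catabolic operons (1.80e-08) and fimbriae (5.70e-06) stood above, each with adjusted p = 0.144 with an estimated correlation. Excision repair in mfd- includes the disrupted mfd gene, whose total changed by -2.044. In uvrD- ribosomal proteins (4.21e-19), flagella (4.19e-16), RNA polymerase and translation factors (6.56e-06), the LexA regulon (9.20e-05), respiration (17 of 36 lower and 1 higher, 18 and 1 adjusted over the list alone; 4.72e-04) and ATP synthase (5 of 9 lower, also adjusted over the list alone; 0.00985) stood below, with adjusted p = 0.206, 0.207, 0.206, 0.206, 0.230 and 0.326 with an estimated correlation. Catabolic operons (0.00535) and fimbriae (0.00694) stood above, with adjusted p = 0.340 and 0.326 with an estimated correlation. The LexA regulon in uvrD- includes the disrupted uvrD gene, whose total changed by -3.255.

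EdgeR called 474 genes lower and 40 higher in total repair in mfd-, and 980 lower and 816 higher in uvrD-. These counts, the list counts and the genes below come from the fit without the experiment number as a block. With library totals in place of TMM the splits were 402 lower and 154 higher, and 821 lower and 1091 higher. The median of all genes moved from 0.05 to 0.12 in mfd- and from 0.01 to 0.13 in uvrD-, and the list medians above kept their signs. With the experiment as a block, mfd- had 708 lower and 312 higher, 1020 in all against 514. Without single libraries the 514 were 255 (WT experiment 1), 241 (mfd- experiment 1) and 223 (mfd- experiment 2). The 1796 of uvrD- were 1128 without WT experiment 2 and 951 without uvrD- experiment 2. In mfd-, the ribosomal protein gene rpsU (3208803 to 3209018) fell by 3.30 (SE 0.382, edgeR adjusted p = 1.94e-04), secG by 3.13 (3.25e-05), the universal stress protein gene uspG by 3.05 (1.29e-05), rpmI by 2.95 and rpmA by 2.82. The largest rises in mfd- were atpI (1.05), yaiS (0.97), yffB (0.84), hybD (0.84) and ybcN (0.81), each lost without WT experiment 1 (edgeR adjusted p of 0.0960, 0.195, 0.142, 0.0709 and 0.266). Each was lost without further libraries: atpI without WT experiment 2 (0.0866) or mfd- experiment 2 (0.140), yaiS without mfd- experiment 1 (0.160) or 2 (0.0797), yffB without WT experiment 2 (0.202) or mfd- experiment 1 (0.49, 0.328), hybD without WT experiment 2 (0.192) or mfd- experiment 1 (0.252), and ybcN without mfd- experiment 1 (0.138) or 2 (0.166). The calls of yffB, hybD and ybcN were also lost without uvrD- experiment 1 (0.0790, 0.0624 and 0.0683) or 2 (0.0798, 0.0613 and 0.0687), and with only mfd- and WT in the fit (0.0651, 0.0543 and 0.0546). Without a minimum count yffB had an edgeR adjusted p of 0.0503. In uvrD-, the peptide deformylase gene def (3431712 to 3432221) rose by 2.01 (SE 0.190, edgeR adjusted p = 1.82e-05), with nanQ (2.04), yjbT (1.84), an unnamed entry at 2468837 to 2469127 (1.81) and smg (1.78). The flagellar regulator gene fliZ (1998497 to 1999048) fell by 4.20 (edgeR adjusted p = 1.01e-06), ssrA by 4.09, the small RNA gene glmY by 3.93, and tpr, whose reads are uncertain, by 4.51. The unnamed entry at 3698159 to 3698224 fell by 5.01. In phr-, edgeR called 0 genes higher and 1 lower, with 70 at an unadjusted p under 0.05, and that gene was phr itself (-1.86, SE 0.166, adjusted p = 6.46e-04). The count was 4 without phr- experiment 1, and 2 with DESeq2 or with the experiment as a block. By edgeR over all genes phr was the only list member called. Adjusted over the list alone, 3 fimbrial genes were also higher, and DESeq2 over all genes called 1 fimbrial gene higher. Camera on the phr- totals placed flagella (mean -0.19 from other genes, adjusted p = 8.65e-09), outer membrane proteins (-0.14, 0.0273) and excision repair, which holds phr (-0.25, 0.0273), below other genes, and fimbriae above (0.10, 0.00261). With an estimated correlation these had adjusted p = 0.501, 0.354, 0.354 and 0.501.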

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

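The plus-strand excess, its tests on disrupted genes and repeated sequence, the rank correlation of uvrD- with WT, the removal of the excess from the risen genes and the choice of genes named in this part were decided only after the results were seen.

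Genes whose TS/NTS changed in opposite directions in mfd- and uvrD-, with a direct test of mfd- against uvrD- past the threshold, numbered 122 with a fall in mfd- and a rise in uvrD-, and 2 with the reverse. More genes changed the same way in both strains, 354 lower and 32 higher, of which 113 and 6 also passed the direct test. Independent calls would share 222 and 8.81 in opposite directions and 203 and 9.62 in the same, so the 122 and the 2 are fewer than that and the 354 and the 32 more. Both contrasts use the same WT libraries, and part of the excess in the same direction may come from them. In 20 simulations with no difference between strains 0 calls were shared in the same direction. These simulations made on average only 0.15 calls in mfd- and 0.1 in uvrD-. The 0 therefore cannot show how many shared calls come from the WT libraries when many genes change. Over all genes the simulated changes of the strains had a covariance of 0.1 and a correlation of 0.499, against 0.413 and 0.351 observed. The ribosomal protein gene rplO (-1.32 in mfd-, 5.00 in uvrD-), the aerotaxis gene aer (-2.23, 2.25), the iron regulator gene fur (-1.73, 2.10), the isoleucyl-tRNA synthetase gene ileS (-1.26, 1.83) and the RNA polymerase gene rpoB (-1.25, 1.48) were among the 122. The 2 were the hydrogenase maturation gene hypC (2849886 to 2850158), at 1.38 (SE 0.360) in mfd- and -1.55 (SE 0.371) in uvrD-, and the gluconate kinase gene idnK (4492646 to 4493209), at 0.73 (SE 0.238) and -1.32 (SE 0.251). Their direct differences were 2.93 (edgeR adjusted p = 9.30e-05) and 2.06 (6.58e-05). By camera, 9 gene lists stood apart from the other genes in mfd- against uvrD-, 6 below and 3 above them. The 3 above were prophage genes, catabolic operons and fimbriae, whose own mean changes were -0.33, -0.26 and -0.21. None of the 9 calls held with an estimated correlation (smallest adjusted p = 0.261).

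Every library had more reads on the plus than on the minus strand of the chromosome, by 0.27 to 0.42 on the log2 scale. Base composition that follows replication would change sign between the replication arms of the chromosome, but the lowest value over 8 libraries and both arms was 0.164, which excludes it as the whole of the excess. Placement of reads by the aligner stayed open. In the disrupted genes 56.9% of the 1569 reads left in the mutants' own libraries lay on the plus strand (95% interval 54.4 to 59.4). By gene these were 212 of 334 reads in phr, 464 of 857 in mfd and 217 of 378 in uvrD. Other named entries had 55.4%, within that interval, so the share cannot tell misplaced reads from ordinary ones. Reads of repeated sequence lay almost wholly on the plus strand (at least 96.8% in each of the 10 entries of 1017 nt, whichever way the entry faced), but with multicopy, rRNA and unnamed entries left out the excess was still 0.246 to 0.394, which excludes them as the whole of it. No biological explanation was tested.

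Ratios in uvrD- lay closer to 1 than in WT. More background reads, if even over both strands and in proportion to each gene's reads, would shrink the ratios but keep the genes in order. The highest Spearman correlation between a uvrD- and a WT library was 0.753, against at least 0.918 within a strain. Correlations of mfd- with WT were as low, at 0.744 to 0.779. A change of order from another cause can go with background, so this cannot tell whether background shrank the ratios. Chance values of the shared WT libraries were set against genes picked by their ratio in phr-, where the top 448 had a median uvrD- change of -1.08 (interquartile range -1.88 to -0.39) and the bottom 448 of 1.09. Chance values of the shared WT libraries do not account for the whole pattern, and a part played by background reads stays open. A change in repair without the UvrD helicase is a hypothesis that these libraries cannot test further.

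The 63 genes with a higher TS/NTS in mfd- had a median NTS change of -0.93 and a median TS change of 0.51, and 42 of them were NTS-ward in WT. Transcription of the opposite strand from an adjacent gene may underlie this: 49 of the 63 (77.8%) had an immediate neighbour on the opposite strand, against 2137 of the other 4415 (48.4%), an odds ratio of 3.73 (95% interval 2.02 to 7.34, Fisher exact p = 2.82e-06). With the plus-strand excess removed, 60 of the 63 were still called. This took out 1 value per library, with means of 0.37 in WT and 0.31 in mfd-, so few calls could change. The difference in excess between the arms in mfd-, given below, was not removed. Transcripts were not measured, so antisense transcription stays a hypothesis.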

How the results depend on the processing

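The removal of the plus-strand excess and the leaving out of multicopy and unnamed entries were added after the data were seen. The TT correction was not run, since a genome was not used here. The experiment number as a block gave 1866 genes changed in mfd- and 1795 in uvrD-. With it these strand ratios passed (edgeR adjusted p): in WT uvrB (0.0154) and lacI (0.0346), in mfd- ymfD (0.000725), rplB (0.0216), tpiA (0.0471) and lacI (0.0491), and in uvrD- ybgQ (0.0111), rpmA (0.0227) and elfC (0.0452), while flagella in phr- did not (camera adjusted p = 0.0504). Other alternatives in which strand ratios passed that did not in the main fit were these (edgeR adjusted p unless another tool is named). In mfd-, ymfD passed in DESeq2 (DESeq2 adjusted p = 0.0365) and with only the 2 strains fitted (0.0338), and rplB with only the 2 strains (0.0339), without near-identical copies (0.0498) and without copies and unnamed entries (0.0484). In uvrD-, rpmA passed in DESeq2 (0.0406), in limma with 5 reads added (0.0238) and with only the 2 strains (0.0187), and ybgQ in DESeq2 (0.0479), with only the 2 strains (0.00378) and with the excess removed (0.0441). In WT, lacZ and uvrB passed with the excess removed. Without phr- experiment 1 and without 2, uvrB in WT (0.00604, 0.00591), rplB (0.0258, 0.0263) and ymfD (0.0142, 0.0144) in mfd-, and rpmA (0.0450, 0.0456) and ybgQ (0.0153, 0.0154) in uvrD- passed. So did rplB without mfd- experiment 1 (0.0314), ymfD without WT experiment 2 (0.0151) or mfd- experiment 1 (0.0114), ybgQ without WT experiment 1 (0.0102) and rpmA without uvrD- experiment 1 (0.0225). Apart from single libraries left out, gene values kept direction and call in 1363 cases, lost the call in 15, gained it in 22 and changed sign in 6. List values did so in 324, 33, 1 and 2. With single libraries left out, the counts were 1084, 70, 15 and 15 for genes and 454, 14, 4 and 8 for lists. Low counts limit single genes such as rpmF, with 2 NTS reads in WT.

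These changed, and the cause was not tested. The mfd- change of ybgQ (0.001) was -0.001 in limma with 1 read added, -0.002 with 5, and 0.000 with the block. With the excess removed, the mfd- changes of lacZ, lysA and metH were 0.003, 0.015 and -0.056, and amino acid biosynthesis in WT stood at 0.013. Prophage genes in WT stood at 0.075 with at least 50 reads. Total repair in phr- gave 2 genes with DESeq2 and 2 with the block, and in mfd- 1020 with the block. The share difference within experiments was -12.36 points (exact permutation p = 0.0625, the smallest 16 assignments give). With an estimated correlation 1 list call of 32 held.

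Leaving out each library in turn gave these ranges. Genes called were 1816 to 2960 for TS against NTS in uvrD-, 0 to 2 for the phr- change, 606 to 1595 for the uvrD- change and 1353 to 2357 for mfd- against uvrD-. For total repair they were 1 to 4 in phr-, 223 to 717 in mfd- and 951 to 2006 in uvrD-. The share difference ran from -13.27 to -11.44. In mfd-, lacZ ran from -0.267 to 0.139, rhaA from -0.348 to 0.05, lysA from -0.126 to 0.025, metH from -0.149 to 0.168 and ybgQ from -0.525 to 0.524. In uvrD-, uvrB ran from -0.317 to 0.067, uvrC from -0.28 to 0.341, rplA from -0.206 to 1.126 and tar from -0.782 to 0.331. Among lists, prophage genes in WT ran from -0.02 to 0.015 and flagella in phr- from -0.321 to 0.003. In uvrD-, respiration ran from -0.127 to 0.048, amino acid biosynthesis from -0.065 to 0.04, RNA polymerase and translation factors from -0.256 to 0.152 and flagella from -0.119 to 0.335.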

Other observations

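The tests in this part, on orientation and on single strands, were chosen only after the results were seen.

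Genes transcribed in the direction of replication had a median TS/NTS change of -0.65 in mfd- (2454 genes, 895 lower), and genes facing replication -0.41 (2024 genes, 555 lower). Per library, the median of the first group minus that of the second was -0.197 ± 0.013 in mfd- (n = 2) and 0.003 ± 0.054 in the other strains (n = 6), with an exact permutation p of 0.0357 over 28 assignments. The same numbers can be read without genes: the plus-strand excess of the arm read from origin to terminus along the coordinates, minus that of the other arm, was 0.188 and 0.202 in the mfd- libraries and -0.088 to 0.048 in the others. Gene direction and chromosome strand within an arm were not separated here. Without members of the gene lists the values by orientation were -0.219 and -0.073, with the same exact permutation p of 0.0357. Both permutation tests ignored the experiment number and took the libraries of a strain as separate units. Permuting within each experiment, as for the template-strand share, cannot give a p this small and was not done here. Tested by strand, edgeR called 1203 genes lower and 47 higher in TS reads in mfd-, and 38 lower and 63 higher in NTS reads. The median change over all genes in mfd- was -0.20 in TS and 0.37 in NTS reads. Reads are relative within a library, so a loss of TS repair and a gain of NTS repair cannot be told apart. In uvrD- edgeR called 761 lower and 791 higher in TS reads, and 857 lower and 794 higher in NTS reads.

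The rRNA genes share reads among copies, and their values are uncertain. The median log2 TS/NTS of the 7 rrs genes was -5.87 ± 1.13 in WT, -6.40 ± 0.80 in mfd- and -2.79 ± 0.75 in uvrD- (SD, n = 2 each). Read density in the tenth of the chromosome around the origin was 1.47 to 1.86 times that around the terminus over the 8 libraries.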
